A study of Caenorhabditis elegans with 16 samples.

How the data were processed

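Messenger RNA was sequenced from whole larvae of the wild-type Caenorhabditis elegans strain N2 at each hour from 1 to 16 h after arrested first-stage (L1) larvae were placed on plates with bacterial food (OP50) at room temperature. Each hour had 1 library, 16 in all, so there were no replicates of any time point, and the labels do not say whether the hours came from separate cultures. Per the labels, larvae were synchronised by an egg preparation followed by incubation in M9 buffer and collected by washing with M9. RNA was extracted with Trizol and phenol-chloroform, and stranded mRNA libraries were read from 1 end with 50 cycles on a HiSeq2500. The submitters' notes give the genome build ce10. The aligner, the counting program, the gene annotation and the use of the strand in counting are not stated.

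The deposited table held raw read counts that the authors had made per gene, for 20392 genes with WormBase identifiers, beside a width column. All values were whole numbers, 0 count columns were left unmatched to a library, and no scaling had been applied. Symbols were taken from the identifier table supplied with the reference annotation and were found for 19182 of the 20392 genes and for 14154 of the 14679 genes tested. The reference annotation is for another build than ce10, so no coordinates are given. Totals ranged from 26810459 to 34539829 counts per library, and 3 counts in a single library corresponded to 0.0811 to 0.122 CPM, the usual per-library scaling of counts.

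Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with at least 10 counts in at least 4 libraries, whichever they were, were kept. CPM were scaled by the trimmed mean of M values (TMM). Hours were grouped by their labels into 4 windows of 4 libraries each: 1 to 4 h, 5 to 8 h, 9 to 12 h and 13 to 16 h. The window means were compared by edgeR's quasi-likelihood test in a fit of all 16 libraries, which is two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. The spread within a window holds both noise and change within the window, so p-values measure only the spread between these libraries. A time course was tested as a natural cubic spline of the hour with 3 degrees of freedom. Genes that rose then fell were higher in the 5 to 8 h or the 9 to 12 h window than in the first window and lower in the last window than in that middle window, both at the threshold, and genes that fell then rose were counted in mirror image.

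The windows, the tests, 39 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered ribosomal proteins, translation factors, ribosome biogenesis, tRNA synthetases, DNA replication, cell cycle and mitosis, histones, cuticle collagens with their furrow and annulus subsets, molting, molting regulators, hedgehog-related genes, heterochronic genes and targets of starvation signalling. They also covered the glyoxylate cycle with trehalose synthesis, glycolysis, oxidative phosphorylation, fatty acid synthesis, fat breakdown, the proteasome, aspartic and cysteine proteases, intestine, the vacuolar ATPase, muscle, neurons, neuropeptides, insulin-like peptides, cilia, germline, and seam cells with epidermis. The remaining lists were lysozymes and saposins, C-type lectins, caenacins, detoxification enzymes, and chaperones and enzymes of collagen processing in the endoplasmic reticulum (ER). Heat shock proteins, and markers of adults and of embryos that a larval sample should lack, were the last. Some genes stand on more than 1 list. Lists were tested with camera at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, which asks whether members move one way on balance without comparing them with other genes. Adjustment was over the lists of a comparison.

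Named genes were the 12 largest rises and 12 largest falls between 13 to 16 h and 1 to 4 h. Added were the 6 largest of each for every step between neighbouring windows, and 10 genes that rose then fell. Each had a mean of at least 5 CPM and a symbol of letters, a hyphen and a number. The rises and falls also had windows without overlap, which was not required of the genes that rose then fell. Up to 4 members of each list with the smallest p-value and 15 regulators and markers of larval development completed the rule. Fold ratios of genes near the detection limit were taken from summed scaled counts with 95% intervals. Such intervals and the floor of 3 counts cover counting error only. The hour of the highest CPM of furrow and annulus collagens was compared by a two-sided exact permutation test.

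The tests were tried on simulated data in which 200 genes were changed by known folds, 50 for each fold. In the comparison of the last with the first window, 46% of genes changed by 1.5-fold, 90% of those changed by 2-fold and all those changed by 4-fold or 8-fold were recovered, with 12 false calls among 14679 genes. For genes made to rise then fall or, in mirror image, to fall then rise, 40% were recovered at 2-fold and 96% at 4-fold, with 0 false calls. The spline test recovered 8% of these genes at 1.5-fold, 40% at 2-fold and 94% at 4-fold, with 3 false calls. All other simulated genes were unchanged, and the spread of each gene was set by the trend over genes. Recovery and false calls may therefore differ in the real libraries, where many genes also change within a window. Alternatives were median-of-ratios scaling, TMM without the 50 most abundant genes, other count filters, DESeq2 with its default dispersion fit, limma-voom, other windows and splines, and leaving out each library in turn. Reads shared between similar genes, such as collagens, histones and actins, were counted in a way the labels do not describe. Splicing, antisense reads and changes below the level of the gene were left out because the table holds 1 count per gene.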

Results

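Messenger RNA counts were collected for larvae of the Caenorhabditis elegans strain N2 at every hour from 1 to 16 h after arrested L1 larvae were plated. The 16 libraries, 1 per hour, fell by their labels into windows of 1 to 4, 5 to 8, 9 to 12 and 13 to 16 h with 4 libraries each. Totals ran from 26810459 counts at 13 h to 34539829 at 8 h, and 16705 to 17623 genes had at least 1 count. The 10 most abundant genes held 5.07 to 6.53% of the counts of a library. The series asks how gene expression changes with time after plating. Values below are means of the 4 libraries of a window in CPM ± SD unless stated, and the SD includes change within the window. A value without a unit in parentheses after a gene is its log2 fold change, with its SE where ± follows.

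Libraries lay along a curve in the order of their hours, which after 12 h turned back along the first principal component only. On the second component 14 h was at -97.1, on the other side from 10 h at 89.1. The first principal component held 55.8% of the variance and the second 22.6%. Across genes, the log2 values of neighbouring hours correlated with r between 0.963 (13 and 14 h) and 0.994. The lowest r of any pair was 0.757, between 1 and 12 h. The 16 h library had r = 0.948 with the 7 h library and 0.857 with the 12 h library, and the 13 h library had 0.831 and 0.969. The 14 h library had 0.865 and 0.907 and the 15 h library 0.911 and 0.861, so the last window joined unlike libraries. Genes are not independent replicates, and these correlations describe similarity only.

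**Figure D1:**
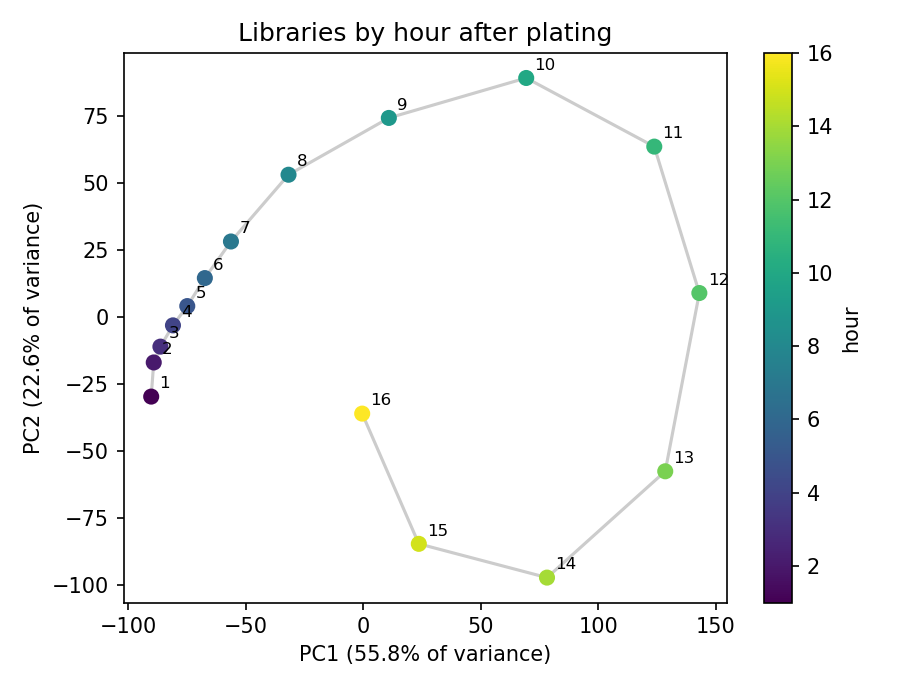
Each point is 1 library placed by the first (x axis, 55.8% of variance) and second (y axis, 22.6%) principal components of log2 CPM, coloured and numbered by hour after plating. Hours 1 to 12 follow a curve, and hours 13 to 16 turn back towards the earlier libraries.

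The molting regulators nhr-23, myrf-1, blmp-1, grh-1 and lin-42 each had their highest value between 9 and 11 h. nhr-23 (WBGene00003622), a nuclear hormone receptor required for molting, went from 8.7 CPM at 1 h to 233 CPM at 9 h and 5.78 CPM at 13 h. myrf-1, a membrane-bound transcription factor that controls molting, reached 1064 CPM at 9 h. lin-42 (WBGene00018572), the Period-like timing gene, went from 3.1 ± 2.14 CPM at 1 to 4 h to 1102 CPM at 11 h, and grh-1, the Grainyhead factor of the epidermis, reached 225 CPM at the same hour. The furrow collagen dpy-7 had its highest value at 10 h (1394 CPM) and mlt-10, a gene needed for molting, at 12 h (1296 CPM). nhr-25, a nuclear hormone receptor of the epidermis, was at 23.9 CPM at 10 h and 103 CPM at 12 h. Across all genes, 12344 of 14679 tested (84.1%) had a time course by the edgeR spline test. Of these, 1376 differed by at least 10-fold between their highest and lowest hour. That count left out every gene with 3 or fewer counts in any library, so it is a lower bound.

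**Figure D2:**
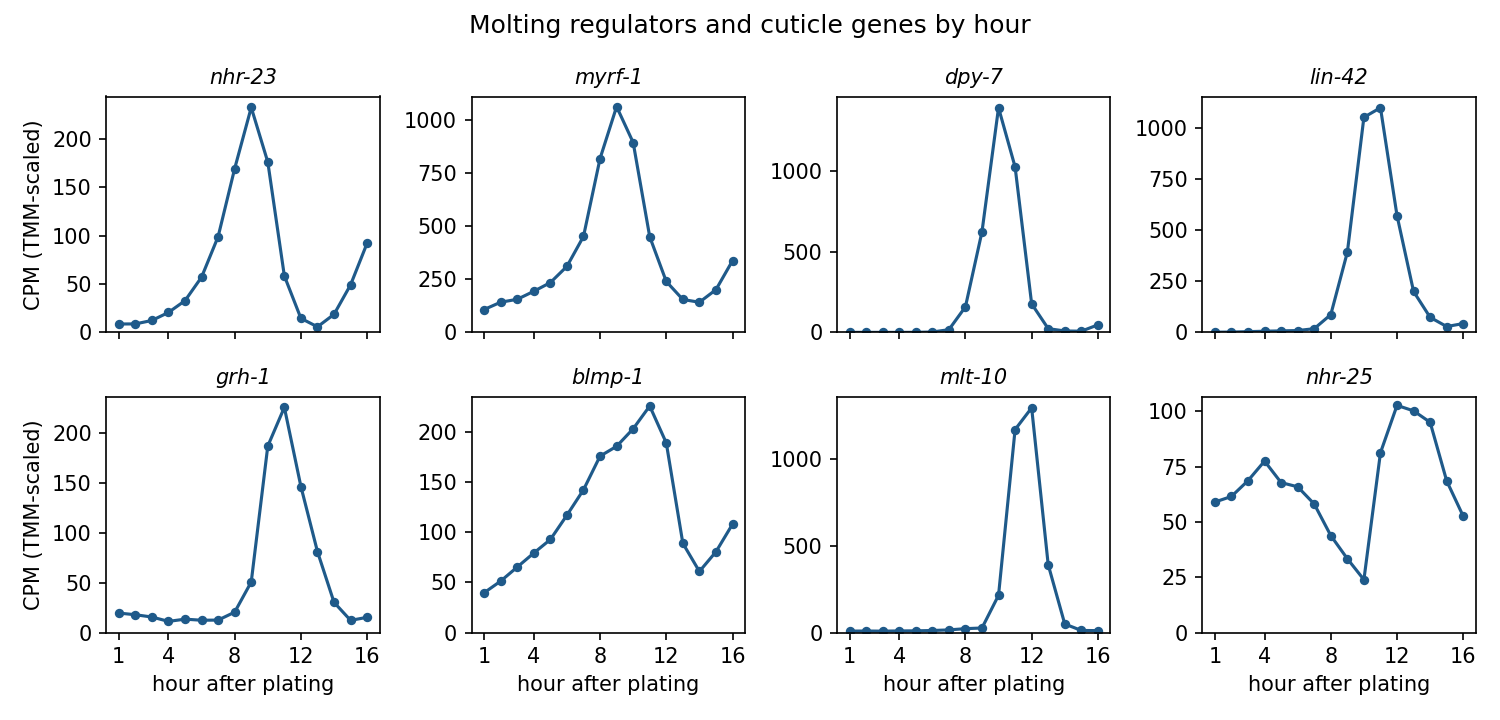
TMM-scaled CPM (y axis) of 8 genes by hour after plating (x axis), 1 library per point. nhr-23 and myrf-1 were highest at 9 h, dpy-7 at 10 h, lin-42, grh-1 and blmp-1 at 11 h, and mlt-10 and nhr-25 at 12 h.

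Between 1 to 4 h and 13 to 16 h, most of the 12 largest rises under the naming rule were of cuticle collagens. They also included acdh-1, the acyl-CoA dehydrogenase of the propionate shunt. acdh-1 (WBGene00016943) went from 0.0709 ± 0.0182 to 970.1 ± 247 CPM, a ratio of 13572-fold (95% interval 7379.8 to 28304) (adjusted p = 4.13e-05, n = 4 and 4). The cuticle collagen col-17 (WBGene00000606) went from 0.0209 to 963 ± 1309 CPM, with a ratio of 42300.4-fold (95% interval 14474 to 205122) that rests on 3 early counts (adjusted p = 0.000241). The collagens col-90, col-41, col-73 and col-54 rose from at most 0.042 CPM to 1120.0, 994, 534 and 226 CPM. The body-shape collagens dpy-4, rol-6 and sqt-1 reached 1421, 455 and 449 CPM, and dpy-4 rose 8148-fold. The hedgehog-related gene grl-16 rose 5472-fold (95% interval 3934 to 7856) to 1437 ± 1603 CPM, and idpc-3 and tag-297 completed the 12 largest rises with 133 and 471 CPM.

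The largest falls were of fmo-2, a flavin-containing monooxygenase, and of the cathepsin B-like protease gene cpr-2. fmo-2 (WBGene00001477) fell from 269 ± 390.3 to 2.75 ± 2.03 CPM (log2 fold change -6.61 ± 1.12 SE, adjusted p = 0.000407) and cpr-2 from 83.5 ± 90.7 to 1.56 ± 0.464 CPM (log2 fold change -5.75 ± 0.73, adjusted p = 6.08e-05). The glutathione S-transferase genes gst-4 and gst-12 fell with log2 changes of -3.13 and -3.44, the aspartyl protease gene asp-12 with -3.38, and scl-5 with -3.30. hrg-7, which encodes a secreted signal of heme status, fell from 796 ± 164 to 137 ± 86 CPM. The F-box gene fbxa-24, the nuclear receptor gene nhr-124, the transthyretin-related gene ttr-39, srlf-30 and the lectin gene clec-42 made up the rest of the 12, with log2 changes of -2.87, -2.57, -2.48, -2.30 and -2.27. Without the library of 1 h the log2 changes of fmo-2, cpr-2 and fbxa-24 were -4.81, -4.68 and -2.02 (adjusted p = 0.000491, 5.26e-05 and 0.000328). Of the regulators chosen in advance, lin-42 rose by 4.81 ± 0.95 (log2, SE), dpy-7 from 0.218 to 21.7 CPM, hbl-1 by 0.67, the cell cycle inhibitor gene cki-1 by 0.96 and the intestinal GATA factor gene elt-2 by 0.53. The heterochronic genes lin-28 and lin-14 changed by -1.76 and -0.62. nhr-23 (1.72 ± 0.85, adjusted p = 0.105), grh-1 (1.11, 0.098), blmp-1 (0.52, 0.0703), myrf-1 (0.48, 0.402), nhr-25 (0.25, 0.597) and the replication clamp gene pcn-1 (-0.36, 0.29) did not pass, except that nhr-23 passed without the 13 h library (adjusted p = 0.0481), blmp-1 without that of 4 h (0.0246) or 14 h (0.0359), and grh-1 without that of 15 h (0.04).

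In all, 4088 genes rose and 3478 fell of 14679 tested (7566, 51.5%), of which 2024 and 1194 changed by at least 2-fold. At an unadjusted p under 0.05, 8546 genes passed. mlt-10 rose by 3.72 ± 1.19 (adjusted p = 0.0188) but did not pass without the 13 h library (1.47, adjusted p = 0.191), and the FOXO gene daf-16, with a log2 change of -0.45 ± 0.16, did not pass without the library of 1, 2, 13 or 14 h (adjusted p = 0.0501 to 0.103). By limma-voom, col-17, col-41, col-54, col-73, col-90, dpy-4, dpy-7, rol-6, sqt-1, tag-297, grl-16 and mlt-10 did not pass, and without the 1 and 2 h libraries gst-12, lin-14, mlt-10 and daf-16 did not.

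Lists of cuticle, molting and related genes rose from the first to the last window. Of the cuticle collagens, 84 tested members rose, 6 fell and 33 did not pass (88 rose and 7 fell adjusted over the list alone), with a median log2 change of 3.51 that did not move when members with a window at 0 were set to their bound. Of the furrow collagens, 6 of 6 tested members rose (6 adjusted over the list alone), and of the annulus collagens, 7 of 9 tested members rose and 1 fell (7 and 1 adjusted over the list alone). Among the annulus collagens dpy-14 fell, and dpy-17 did not pass. Of the molting genes, 23 of 28 tested members rose (24 adjusted over the list alone), among them mlt-8 (0.243 to 155 CPM) and the oxidase gene bli-3 (19.4 to 58.9 CPM). Of the hedgehog-related genes, 49 of 69 tested members rose and 5 fell (50 and 5 adjusted over the list alone), with grl-21 higher (6.95) and grl-9 lower (-2.29). Of the caenacins and epidermal antimicrobial peptides, 15 of 24 tested members rose and 3 fell (16 and 3 adjusted over the list alone), including nlp-33 (31.1 to 220.3 CPM). Of the genes for ER chaperones and collagen processing, 5 of 14 tested members rose (5 adjusted over the list alone), including hsp-4 (129 to 373 CPM). Camera at the preset correlation called all 7 of these lists higher. With an estimated correlation none passed: adjusted p = 0.343 with an estimated correlation for cuticle collagens, 0.388 for molting, 0.502 for the furrow and the ER lists, and 0.498 for the other three. The furrow list lost its preset call without the 4 h library (adjusted p = 0.0539), and the caenacins without the library of 4 or 15 h (adjusted p = 0.053 to 0.0587).

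The proteasome, muscle, germline and several metabolic lists rose as well. Of the proteasome subunits, 31 of 33 tested members rose (32 adjusted over the list alone), such as rpt-6 (0.88 ± 0.18) and pbs-2 (0.79 ± 0.15). Of the muscle markers, 16 of 21 tested members rose (16 adjusted over the list alone), including the troponin gene unc-27 (253 to 732 CPM) and the paramyosin gene unc-15 (1656 to 3254 CPM). Of the germline markers, 15 of 20 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with the Vasa-like helicase gene glh-1 (35.3 to 113 CPM) and the P-granule gene pgl-3 (4.35 to 9.8 CPM). Of the fat breakdown genes, 23 of 44 tested members rose and 3 fell (23 and 3 adjusted over the list alone), for example ech-6 (73.3 to 656 CPM). This list took acdh and ech genes by their symbols and so includes acdh-1 of the propionate shunt. Its changes are therefore not those of fat breakdown alone. Of the glyoxylate cycle and trehalose genes, 7 of 9 tested members rose (7 adjusted over the list alone), led by tps-2, mdh-1 and icl-1, the last of which encodes isocitrate lyase and rose from 42.7 to 303 CPM. Of the glycolysis genes, 13 of 17 tested members rose (13 adjusted over the list alone), such as tpi-1 (0.67) and gpd-2 (0.85), and of the histone genes, 13 of 18 tested members rose (14 adjusted over the list alone). Of the oxidative phosphorylation genes, 19 of 37 tested members rose and 2 fell (19 and 2 adjusted over the list alone), including ucr-2.3 (1.78), and of the cell cycle genes, 12 of 33 tested members rose (10 adjusted over the list alone), including fzr-1 (1.18). These 9 lists were called higher at the preset correlation, and their adjusted p = 0.343 with an estimated correlation for muscle, germline, fat breakdown, glyoxylate, glycolysis and histones, 0.498 for the proteasome, 0.65 for oxidative phosphorylation and 0.669 for the cell cycle. Oxidative phosphorylation lost its preset call without the 16 h library (adjusted p = 0.0577) and the cell cycle without the library of 1 or 13 h (adjusted p = 0.0964 to 0.123). Replication-dependent histone transcripts lack poly(A) tails, which limits what an mRNA library shows of them.

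Lists of ciliary, neuronal, neuropeptide, ribosome assembly and translation factor genes fell. Of the ciliary genes, 20 of 20 tested members fell (20 adjusted over the list alone), such as the kinesin gene osm-3 (-1.03 ± 0.16) and the Bardet-Biedl gene bbs-1 (-1.09 ± 0.15). Of the neuropeptide genes, 9 of 96 tested members rose and 68 fell (11 and 71 adjusted over the list alone), with nlp-49 lower (300.1 to 117 CPM) and nlp-24 higher (17.5 to 435 CPM). Of the neuronal genes, 1 of 24 tested members rose and 15 fell (1 and 15 adjusted over the list alone), including the neuropeptide-processing genes egl-3 (835 to 359 CPM) and egl-21 (681 to 323 CPM). Of the ribosome biogenesis genes, 19 of 23 tested members fell (20 adjusted over the list alone), such as the RNA polymerase I subunit gene rpoa-1 (294 to 157 CPM). Of the translation factors, 4 of 40 tested members rose and 22 fell (5 and 23 adjusted over the list alone), with eif-3.F lower (-0.45) and iff-1 higher (3.03). All 5 were called lower at the preset correlation, with adjusted p = 0.355 with an estimated correlation for cilia, 0.498 for neurons, neuropeptides and ribosome biogenesis, and 0.676 for translation factors. The translation factors lost their preset call without the library of 3, 4, 13 or 14 h (adjusted p = 0.0629 to 0.0973). In all, camera called 21 of 39 lists at the preset correlation (22 at an unadjusted p under 0.05) and 0 at an estimated one (1 unadjusted, smallest adjusted p = 0.343), and fry called 29.

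The remaining 18 lists were not called by camera. Of the ribosomal proteins, 1 of 76 tested members rose and 1 fell (1 and 0 adjusted over the list alone). rpl-11.1 rose (61.6 to 181 CPM), and rpl-25.1 fell (-0.33), though not without the library of 2, 3, 4, 13, 14 or 15 h (adjusted p = 0.0585 to 0.115). In this comparison the list was called lower only without the 1 h library (adjusted p = 0.0163). It was not static, as 75 of 76 members had a time course and its sum was 107184 CPM at 1 h, 164518 at 5 h, 124619 at 12 h and 141131 at 16 h. Camera at the preset correlation called it higher from 1 to 4 h to 5 to 8 h (adjusted p = 3.02e-06, 0.706 with an estimated correlation). In the step to 9 to 12 h it was called lower (adjusted p = 0.000166, 0.766 with an estimated correlation). Of the tRNA synthetases, 3 of 32 tested members rose and 6 fell (3 and 5 adjusted over the list alone), of the DNA replication genes, 5 of 37 tested members rose and 2 fell (3 and 0 adjusted over the list alone), and of the molting regulators, 3 of 10 tested members rose (2 adjusted over the list alone). Of the heterochronic genes, 5 of 12 tested members rose and 2 fell (6 and 2 adjusted over the list alone), with the nuclear receptor gene daf-12 higher (81.6 to 276 CPM). Of the starvation targets, 5 of 17 tested members rose and 3 fell (5 and 3 adjusted over the list alone), with the superoxide dismutase gene sod-3 higher (2.16). Of the proteases, 5 of 21 tested members rose and 10 fell (5 and 11 adjusted over the list alone), and this list was called lower without the 12 h library (adjusted p = 0.0399). Of the intestinal markers, 5 of 14 tested members rose (5 adjusted over the list alone), of the vacuolar ATPase subunits, 4 of 20 tested members rose (3 adjusted over the list alone), and of the seam cell and epidermal regulators, 3 of 9 tested members rose and 1 fell (4 and 1 adjusted over the list alone). Of the lysozymes and saposins, 14 of 36 tested members rose and 8 fell (14 and 8 adjusted over the list alone), with lys-7 higher (35.1 to 182 CPM), and of the heat shock genes, 2 of 10 tested members rose and 1 fell (1 and 0 adjusted over the list alone). Of the fatty acid synthesis genes, 3 of 19 tested members rose and 3 fell (2 and 3 adjusted over the list alone), with a median of -0.06, a mean of 0.13 and a downward camera statistic. Of the insulin-like genes, 5 of 23 tested members rose and 9 fell (5 and 9 adjusted over the list alone), with a median of -0.03, a mean of 0.24 and a downward statistic. Of the C-type lectins, 23 of 121 tested members rose and 32 fell (23 and 31 adjusted over the list alone), with a median of -0.09, a mean of 0.17 and a downward statistic. Of the detoxification genes, 42 of 174 tested members rose and 38 fell (42 and 38 adjusted over the list alone), with a median of 0.15, a mean of 0.08, a downward camera and an upward fry statistic. Of the adult markers only the yolk gene vit-1 had enough counts to be tested, and it rose from 0.163 to 5.77 CPM. Of the embryonic markers med-2 fell (0.946 to 0.203 CPM) and nhr-68, which larvae also express, rose (9.18 to 106 CPM).

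Between 1 to 4 h and 5 to 8 h, the gene for the molting protease inhibitor mlt-11 went from 0.477 to 201 ± 364 CPM, 454-fold (95% interval 358 to 586), and acdh-1 from 0.0709 to 37.1 ± 56.8 CPM, 554-fold (95% interval 301 to 1155), with adjusted p of 0.0093 and 0.00854. The matrix gene sym-1 rose 339.6-fold, the lipocalin-related genes lpr-3 and lpr-6 331-fold and 291-fold, and the patched-related gene ptr-10 429-fold. The largest falls were of fmo-2 (269 ± 390.3 to 3.38 ± 0.86 CPM, log2 change -6.32, adjusted p = 0.00854), of ech-9, which encodes an enoyl-CoA hydratase (-5.28 ± 1.27), of nspe-1 (-3.36 ± 0.82) and of cpr-2 (-3.29 ± 0.64). Without the library of 1 h, where ech-9 was at 226 CPM against 4.14 CPM at 2 h, these 4 log2 changes were -4.52, -1.91, -2.55 and -2.22 (adjusted p = 0.0224, 0.0459, 0.0427 and 0.0224). The glucuronosyltransferase gene ugt-18 (-4.23 ± 1.17) and the collagen gene col-177 (-2.48 ± 0.66) fell too, but did not pass without the library of 1, 7 or 8 h (adjusted p = 0.0563 to 0.176 and 0.0534 to 0.0654), with log2 changes of -1.41, -4.30 and -4.04 for ugt-18 and of -2.17, -2.41 and -2.26 for col-177. The Blimp1-like factor gene blmp-1 rose from 59 ± 17.2 to 132 ± 35.6 CPM (adjusted p = 0.00864). nhr-23, myrf-1 and lin-42 rose by 2.83, 1.60 and 3.30. nhr-23 and myrf-1 did not pass without the library of 1, 2, 3, 7 or 8 h (adjusted p = 0.0673 to 0.107 and 0.0516 to 0.108), nor lin-42 without that of 1, 2 or 8 h (adjusted p = 0.0552 to 0.0897).

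Proteasome and ER genes rose together in this step. Of the proteasome subunits, 32 of 33 tested members rose (32 adjusted over the list alone), such as rpn-7 (114 to 222 CPM), and of the ER list, 12 of 14 tested members rose (12 adjusted over the list alone), including the protein disulfide isomerase gene pdi-2 (934 to 2835 CPM). Of the DNA replication genes, 12 of 37 tested members rose (18 adjusted over the list alone), for example rpa-2 (0.42), and of the cell cycle genes, 14 of 33 tested members rose and 2 fell (23 and 2 adjusted over the list alone), with the cyclin E gene cye-1 (0.77) and efl-1 (0.64) among the rises. Of the molting genes, 13 of 28 tested members rose (13 adjusted over the list alone), led by acn-1 and mlt-8, and of the molting regulators, 4 of 10 tested members rose (6 adjusted over the list alone). Of the neuropeptides, 1 of 96 tested members rose and 67 fell (3 and 76 adjusted over the list alone), of the neuronal genes, 18 of 24 tested members fell (19 adjusted over the list alone), including egl-3 (-0.74), and of the ciliary genes, 8 of 20 tested members fell (15 adjusted over the list alone). Of the ribosome biogenesis genes, 18 of 23 tested members fell (22 adjusted over the list alone), such as dao-5 (457 to 240.2 CPM) and the nucleolar GTPase gene nog-1 (788 to 459 CPM). The vacuolar ATPase had 9 of 20 subunits higher (11 adjusted over the list alone), and 5 with median-of-ratios scaling. Camera at the preset correlation called each of these lists, with adjusted p = 0.357 with an estimated correlation for the proteasome, ER, molting regulator, neuronal, neuropeptide and ribosome biogenesis lists, 0.555 for DNA replication, 0.501 for the cell cycle and molting, 0.52 for cilia and 0.651 for the vacuolar ATPase.

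By edgeR 1831 genes rose and 1859 fell (3690; 419 and 339 by at least 2-fold), and 5864 had an unadjusted p under 0.05. The count was 2044, 1763, 1861 and 1315 without the library of 1, 2, 7 and 8 h. Without both the 1 and 2 h libraries edgeR called 0 genes (2871 unadjusted, smallest adjusted p = 0.131), limma-voom 0 (2948 unadjusted) and DESeq2 1502. Over the 3690 genes, which were picked with those libraries, the median log2 change in the called direction was 0.59 (quartiles 0.42 to 0.88, median SE 0.15) with them and 0.41 (quartiles 0.29 to 0.66, median SE 0.16) without. By limma-voom on all libraries, acdh-1, mlt-11, ptr-10, sym-1, lpr-3, lpr-6, ech-9, ugt-18, mlt-8, lin-42 and nhr-23 did not pass.

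**Figure D3:**
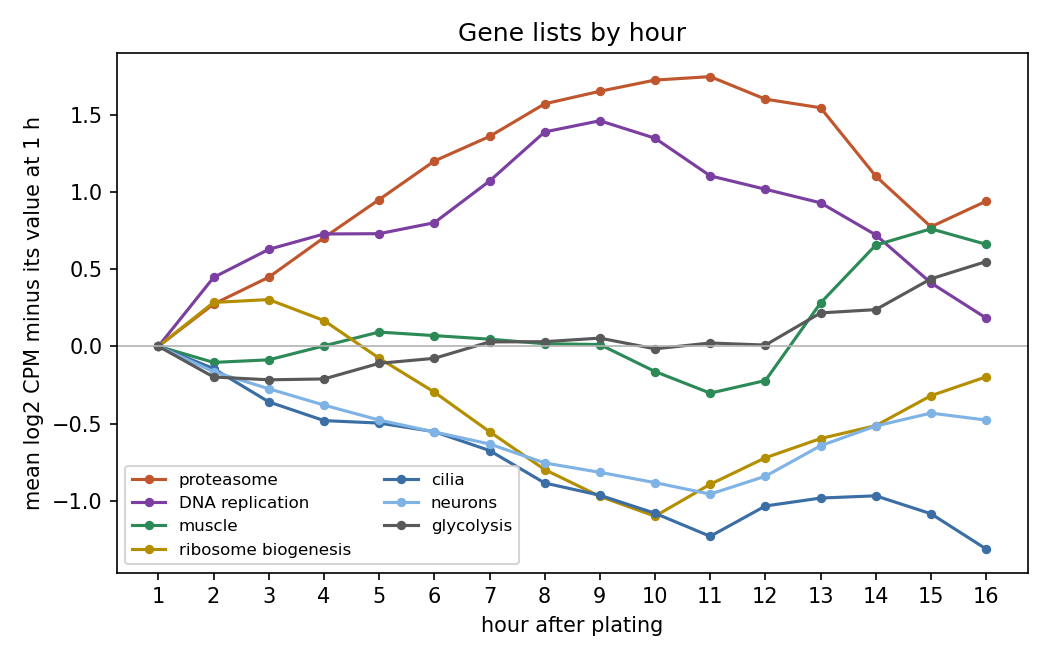
Mean log2 CPM of the members of 7 gene lists minus its value at 1 h (y axis) by hour after plating (x axis), 1 library per point. The proteasome list was highest at 11 h, DNA replication at 9 h and muscle at 15 h, and ribosome biogenesis was lowest at 10 h.

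Between 5 to 8 h and 9 to 12 h, the largest rises were of collagen and hedgehog-related genes that had been near the detection limit. The ground-like gene grl-7 went from 0.0308 to 728 ± 752 CPM, 22504-fold (95% interval 8789 to 82596), and dpy-4 from 0.167 to 2135 ± 2011 CPM, 11915-fold (95% interval 7869.8 to 19013), with adjusted p of 0.00302 and 0.00231. The collagens col-41, col-17 and col-90 reached 1795, 1779 and 1587 CPM from at most 0.117 CPM. The groundhog gene grd-2 had 0 counts at 5 to 8 h and 61.5 ± 66.6 CPM at 9 to 12 h, at least 2523-fold higher against a floor of 3 counts over the window. Other collagens fell: col-160 from 109 ± 48.4 to 3.84 ± 4.9 CPM (log2 change -4.82 ± 1.03) and col-39 from 93.1 ± 64.7 to 4.45 ± 3.45 CPM (-4.38 ± 0.81). col-93 (3.41 to 0.2 CPM) and the receptor tyrosine kinase gene kin-15 (-3.31 ± 0.59) fell as well. col-80 and col-147 fell, with log2 changes of -4.26 and -4.12, but did not pass without the library of 5, 6, 7, 10, 11 or 12 h for col-80 (adjusted p = 0.0619 to 0.0932) or of 2, 3, 5, 6, 7, 10, 11 or 12 h for col-147 (adjusted p = 0.05 to 0.101). grh-1 rose from 14.7 ± 3.87 to 152 ± 75 CPM and lin-42 from 30.6 ± 38.1 to 781 ± 352 CPM. The heterochronic zinc finger genes lin-29 and hbl-1 rose by 2.28 and 0.76, and lin-14 changed by -0.95 (adjusted p = 0.002, 0.00479 and 0.00487).

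Of the cuticle collagens, 60 tested members rose, 11 fell and 52 did not pass (62 rose and 17 fell adjusted over the list alone), with a median log2 change of 2.35, or 2.19 with members that had a window at 0 set to their bound. Of the furrow collagens, 6 of 6 tested members rose (6 adjusted over the list alone), and of the annulus collagens, 8 of 9 tested members rose and 1 fell (8 and 1 adjusted over the list alone), for example dpy-13 (0.52 to 2437 CPM). Of the molting genes, 16 of 28 tested members rose (21 adjusted over the list alone), including the protease gene nas-37 (4.92) and mlt-9 (6.11), and of the hedgehog-related genes, 42 of 69 tested members rose and 5 fell (43 and 10 adjusted over the list alone), including wrt-2 (0.7 to 445 CPM) and qua-1 (5.86). Of the fat breakdown genes, 14 of 44 tested members rose (15 adjusted over the list alone), such as ech-6 (1.48), and of the germline markers, 5 of 20 tested members rose (5 adjusted over the list alone). Of the ribosome biogenesis genes, 17 of 23 tested members fell (21 adjusted over the list alone), such as toe-1 (-0.53), and of the ciliary genes, 12 of 20 tested members fell (14 adjusted over the list alone), such as osm-3 (-0.92). Of the neuronal genes, 2 of 24 tested members rose and 12 fell (2 and 18 adjusted over the list alone), and 8 fell with median-of-ratios scaling. Of the muscle markers, 5 of 21 tested members fell (5 adjusted over the list alone), with the pharyngeal myosin gene myo-2 lower (1507 to 609 CPM). Camera at the preset correlation called each of these lists except muscle (adjusted p = 0.0981), with adjusted p = 0.537 with an estimated correlation for the called lists. By edgeR 1980 genes rose and 1359 fell (3339, 22.7%; 1109 and 312 by at least 2-fold; 5614 at an unadjusted p under 0.05). The count was 1377, 1406, 2050 and 1577 without the library of 5, 6, 7 and 11 h. By limma-voom grl-7, grd-2, dpy-4, dpy-13, col-17, col-41, col-90 and col-93 did not pass.

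Between 9 to 12 h and 13 to 16 h, furrow collagens and molting genes fell, and other collagens moved both ways. dpy-8 fell from 883 ± 687 to 14.6 ± 9.51 CPM (log2 change -5.92 ± 1.24, adjusted p = 0.0035, n = 4 and 4). The hedgehog-related gene wrt-2 fell from 445 ± 356 to 9.5 ± 10.3 CPM, the bZIP factor gene atf-8 from 59.2 ± 51.6 to 1.02 ± 0.594 CPM, and col-128 and mltn-9 with log2 changes of -5.65 and -5.49. dpy-3 fell (-5.63 ± 1.70), but did not pass without the library of 14 or 15 h (-5.39 and -5.35, adjusted p = 0.0609 to 0.0631). The collagens col-146 and col-93 rose 1770.2-fold (95% interval 813 to 4825) and 429.5-fold (95% interval 289 to 671) to 94.1 ± 75.3 and 89.9 ± 59.6 CPM. The hedgehog-related gene grl-21 rose from 0.302 to 201 ± 180.0 CPM (9.35 ± 1.01 log2, adjusted p = 0.000152), and nspb-11, nspb-12 and dct-5 reached 31, 64.6 and 30.9 CPM. blmp-1, grh-1 and lin-42 fell, with log2 changes of -1.25, -2.13 and -3.17. myrf-1 fell (-1.66 ± 0.47), but did not pass without the library of 9 or 14 h (-1.34 and -1.52, adjusted p = 0.0517 to 0.0518). lin-28, which encodes an RNA-binding heterochronic protein, fell (-1.05 ± 0.24) and daf-12 rose (0.83 ± 0.13).

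Muscle, germline and neuronal genes rose in this step. Of the muscle markers, 19 of 21 tested members rose (19 adjusted over the list alone), including the myosin gene unc-54 (4629 to 8446 CPM) and unc-89 (641 to 1364 CPM). Of the neuronal genes, 13 of 24 tested members rose and 1 fell (13 and 1 adjusted over the list alone), with the genes for GABA synthesis and transport unc-25 (38.3 to 159 CPM) and unc-47 (1.31) among the rises. Of the germline markers, 17 of 20 tested members rose (18 adjusted over the list alone), of the ribosome biogenesis genes, 18 of 23 tested members rose (22 adjusted over the list alone), such as nog-1 (312 to 479 CPM), and of the glycolysis genes, 8 of 17 tested members rose (10 adjusted over the list alone). Of the proteasome subunits, 0 of 33 tested members rose and 31 fell (1 and 31 adjusted over the list alone), such as rpn-3 (341 to 220.3 CPM). Of the DNA replication genes, 25 of 37 tested members fell (31 adjusted over the list alone), for example the thymidylate synthase gene tyms-1 (50.6 to 20.2 CPM), and of the cell cycle genes, 3 of 33 tested members rose and 14 fell (3 and 19 adjusted over the list alone), with the cyclin D gene cyd-1 lower (72.9 to 21.3 CPM). Of the furrow collagens, 6 of 6 tested members fell (6 adjusted over the list alone). Of the molting genes, 2 of 28 tested members rose and 13 fell (3 and 14 adjusted over the list alone), with the peroxidase gene mlt-7 (44.3 to 355 CPM) among the rises, and of the ER list, 9 of 14 tested members fell (10 adjusted over the list alone), including pdi-2 (4764 to 1442 CPM). Of the cuticle collagens, 37 tested members rose, 16 fell and 70 did not pass (39 rose and 17 fell adjusted over the list alone), with col-39 higher (4.45 to 1372 CPM). Camera at the preset correlation called each of these lists, with adjusted p = 0.529 with an estimated correlation for all of them. It did not call the annulus collagens (adjusted p = 0.187), of which 1 of 9 tested members fell (0 adjusted over the list alone), with a median log2 change of -0.69. By edgeR 2580 genes rose and 2323 fell (4903, 33.4%; 1040 and 747 by at least 2-fold; 6497 at an unadjusted p under 0.05). Without the 13 and 14 h libraries col-128, dpy-3 and myrf-1 did not pass.

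Genes that rose then fell numbered 1718, and 1597 of them (93.0%) had their highest value between 9 and 12 h. The rule needs a lower mean at 13 to 16 h, so genes that peaked in that window could hardly be called. The share therefore does not show when genes in general peaked. The furrow collagens dpy-8, dpy-3 and dpy-2 peaked at 10 h with 1703, 1115 and 1542 CPM, and so did the lipocalin-related gene lpr-4 (1719 CPM), col-128 (257), atf-8 (131), mltn-9 (303), mltn-1 (204) and idpp-1 (285). wrt-2 peaked at 11 h with 810.1 CPM. Of the lists, 31 of 33 proteasome subunits rose then fell with a median peak at 11 h, 19 of 37 DNA replication genes with a median peak at 9 h, 14 of 33 cell cycle genes at 9 h, 9 of 14 ER genes at 10 h and 13 of 28 molting genes at 10 h. Genes that fell then rose numbered 1287, including 18 of 23 ribosome biogenesis genes and 13 of 24 neuronal genes. The first count was 1139 without the 15 h library and the second 797 without the 10 h library.

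**Figure D4:**
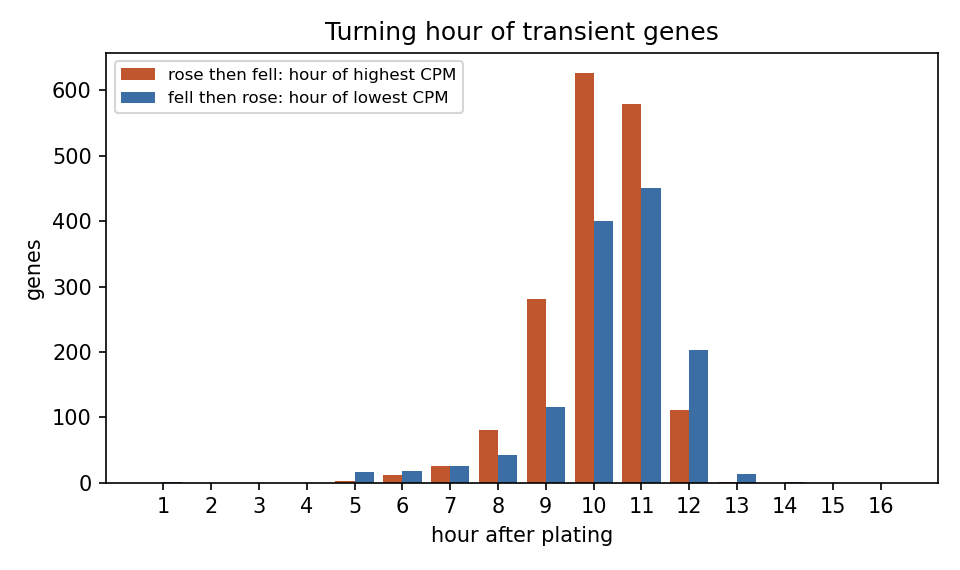
Number of genes (y axis) that rose then fell, by the hour of their highest CPM, and that fell then rose, by the hour of their lowest CPM (x axis, hour after plating). The first group was largest at 10 h (626 genes) and the second at 11 h (451 genes). Both rules need a return by 13 to 16 h, so turning hours in that window are nearly left out by construction.

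The furrow collagens all had their highest value at 10 h (6 genes), and the annulus collagens at a mean of 10.2 ± 3.53 h (SD, 9 genes). The difference of -0.222 h gave a two-sided exact permutation p of 0.987 over 5005 permutations. The annulus list included dpy-14, which was never above 0.595 CPM (at 1 h), and dpy-17, which peaked at 2.42 CPM. With genes of at least 5 CPM at their peak, a limit chosen after the values were seen, the annulus mean was 11.6 ± 0.535 h (7 genes), the difference was -1.57 h and the two-sided exact p was 0.000583 (1716 permutations). Among these, sqt-3 reached 5779.9 CPM at 11 h, and dpy-13 and dpy-4 reached 5033 and 4268 CPM at 12 h. Genes of a list are not independent replicates. Of 97 cuticle collagens with at least 5 CPM at their peak, 9 peaked at 10 h, 14 at 12 h, 21 at 14 h and 9 at 16 h, and the sum over all cuticle collagens went from 2269 CPM at 1 h to 52509 CPM at 12 h and 12102 CPM at 16 h.

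**Figure D5:**
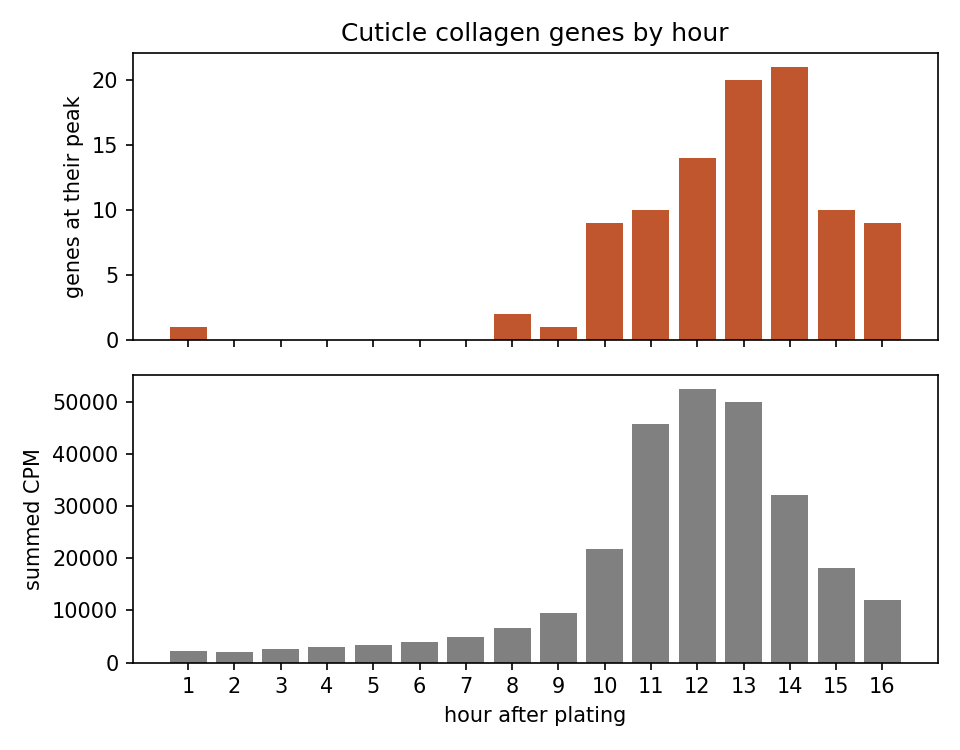
Upper bars give the number of cuticle collagen genes with their highest CPM at each hour after plating (97 genes of at least 5 CPM at their peak), and lower bars the summed CPM of cuticle collagens. The most frequent peak hours were 14 h (21 genes) and 13 h (20 genes), and the sum was highest at 12 h with 52509 CPM.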

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

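Chosen after the results were seen were the tests of 15 to 16 h against 1 to 4 h, 13 to 16 h against 3 to 4 h, 5 to 8 h against 3 to 4 h, 15 to 16 h against 9 to 12 h, and collagens of at least 5 CPM at their peak. Of 191 recalculations of the counts and the collagen comparison, 173 stayed within 1.5 times the reported count or on the same side of the threshold, 17 were smaller or no longer passed and 1 newly passed. Which direction held more genes changed in some of them. For 13 to 16 h against 1 to 4 h fewer genes rose than fell by limma-voom (3397 and 3462), in a fit of only the 8 libraries (3037 and 3074) and against 3 to 4 h (2457 and 2782). For 13 to 16 h against 9 to 12 h this was so with 15 to 16 h (2630 and 2696) and without 10 h (1696 and 1727). For 5 to 8 h against 1 to 4 h, with 1831 and 1859 in the main fit, more rose than fell in TMM scaling without the 50 most abundant genes (1863 and 1809), without a filter (1670 and 1560), at a log2 change of at least 1 (419 and 339) and without 1, 4, 5, 6, 7 or 10 h (1042 and 1002, 2291 and 2259, 1893 and 1878, 1445 and 1335, 958 and 903, 1729 and 1584). A straight line in place of the spline gave 6814 genes with a time course, since it cannot follow a rise and fall. A log2 change of at least 1, which by its construction lowers counts, left 3218 genes for 13 to 16 h against 1 to 4 h, 758 for 5 to 8 h against 1 to 4 h, 1421 for 9 to 12 h against 5 to 8 h and 1787 for 13 to 16 h against 9 to 12 h. The comparison of 5 to 8 h with 3 to 4 h, in a fit without 2 libraries, had 0 genes by edgeR (2871 at an unadjusted p under 0.05), 0 by limma-voom (2948) and 1502 by DESeq2, and the median change of the genes called with all libraries went from 0.59 (SE 0.15) to 0.41 (SE 0.16). Camera with an estimated correlation called 0 lists (1 at an unadjusted p under 0.05), and fry, which does not compare members with other genes, called 29. The 2 camera tests differ in the correlation they assume. For the 21 lists called at the preset correlation of 0.01, the estimates ran from 0.13 (cuticle collagens) to 0.926 (furrow collagens). Collagen peaks differed by -1.57 h (exact p = 0.000583) with genes of at least 5 CPM, because dpy-14 and dpy-17 were left out.

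Leaving out 1 library gave 6437 (without 2 h) to 7699 (without 16 h) genes for 13 to 16 h against 1 to 4 h, 1315 (without 8 h) to 4550 (without 4 h) for 5 to 8 h against 1 to 4 h, 1377 (without 5 h) to 3981 (without 13 h) for 9 to 12 h against 5 to 8 h, and 3314 (without 15 h) to 5707 (without 13 h) for 13 to 16 h against 9 to 12 h. It gave 1139 (without 15 h) to 2196 (without 13 h) genes that rose then fell, 797 (without 10 h) to 1560 (without 13 h) that fell then rose, 11798 to 12572 with a time course and 18 to 22 lists. The count for 5 to 8 h against 1 to 4 h was also 2044, 1763 and 1861 without 1, 2 and 7 h, and that for 9 to 12 h against 5 to 8 h was 1406, 2050 and 1577 without 6, 7 and 11 h. DESeq2 called 8364, 5028, 4611 and 5838 genes in the 4 comparisons and limma-voom 6859, 3771, 2575 and 4660. Of 573 named results that passed, 126 did not pass in some fit without 1 library and 215 under some other setting. Other scalings moved the median of all genes by -0.0125 to 0.0149 (log2), and the protease list between 5 to 8 h and 1 to 4 h was the list whose median changed sign. No paired analysis was possible because each hour has 1 library. With 3 counts in 1 library at 0.0811 to 0.122 CPM, depth limited only the lowest values, and the fitted folds of genes below that level depend on the prior count.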

Other observations

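The tests of the rise at 16 h and of the ciliary, neuronal and neuropeptide lists were chosen after the results were seen, and the other splits of the libraries were planned. The genes of the next 2 paragraphs that stand outside the rule for naming were chosen after their values were seen.

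Several genes of the propionate shunt rose. acdh-1 went from 0.0541 CPM at 1 h to 121 CPM at 8 h and 1244 CPM at 13 h. hphd-1, the hydroxyacid-oxoacid transhydrogenase gene, went from 16.8 CPM at 1 h to 559 CPM at 11 h, and hach-1, the hydrolase gene of the same route, from 44.5 to 195 CPM at 13 h. Between 1 to 4 h and 13 to 16 h their log2 changes were 13.66, 4.31 ± 0.45 and 1.63 ± 0.17 (SE, n = 4 and 4), with adjusted p of 4.13e-05, 1.86e-05 and 1.66e-05. nhr-68, a nuclear receptor that activates the shunt, rose by 3.53 ± 0.32 (adjusted p = 9.31e-06). Its partner nhr-10 was at -0.04 (adjusted p = 0.755) and alh-8, a later enzyme, at 0.18 (adjusted p = 0.32). pcca-1, of the vitamin B12-dependent route, rose by 0.66 ± 0.11.

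Several genes were highest at 1 h and dropped within 1 to 2 h. fmo-2 was at 844, 181 and 37.5 CPM at 1, 2 and 3 h, ech-9 at 226 and 4.14 CPM at 1 and 2 h, and cpr-2 at 215 and 73.3 CPM. Between 1 and 2 h 108 genes were at least 2-fold higher and 166 lower, and between 2 and 3 h 24 and 19. The collagen genes col-39 and col-147 fell and returned: col-39 was at 209 CPM at 4 h, 1.44 CPM at 11 h and 2328 CPM at 15 h, and col-147 at 71.3 ± 52 CPM at 1 to 4 h, 9.43 ± 13.6 CPM at 9 to 12 h and 824 CPM at 16 h. The hedgehog-related gene grl-21 reached 402 CPM at 15 h. vit-1, a yolk gene of adults, was at 11.5 CPM at 13 h and 1.33 CPM at 16 h. Of the genes higher at 9 to 12 h than at 5 to 8 h, 1432 had a mean of at least 5 CPM, and at 16 h they had lost a median of 81.0% of that change (quartiles 45.4 to 107), and 1012 such lower genes 88.4% (33.3 to 136).

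Genes with a steep first wave (a peak of at least 5 CPM, 10-fold above the mean of 1 to 4 h and above 14 h) that peaked at 9 or 10 h were higher again at 16 h than at 14 h, with a median log2 ratio of 1.27 among 124 (105 higher) and of -0.59 among 117 that peaked at 11 h or later (33 higher). Over all 1596 genes that rose then fell and reached 5 CPM, the median was 0.02 (840 higher). Both steep sets were picked for a low value in the 14 h library. This by itself favours a ratio above 0, so the ratio of 1 set alone is no test of a rise. The difference of 1.85 between the sets cannot come from scaling of the 16 h library, which moves both sets alike. It does not test whether scaling shifted the ratios of both sets. The median of 0.02 over all 1596 genes showed no common shift as large as 1.27. The steep genes would need 79.0% of larvae at the 7 h stage (quartiles 46.8 to 160). This argued against larvae of that stage, as 902 of 5916 other genes lay below the median need and 88 below the first quartile. Younger larvae of later stages cannot be told apart from a second rise: the need was 24.8% at the 8 h stage (24 of 5941 other genes below the median and 8 below the first quartile), 5.80% at 9 h (quartiles 2.91 to 11.6; 8 and 0 of 5987) and 3.15% at 10 h (quartiles 0.959 to 8.69; 68 and 13 of 6058), and no single share gives all values. A second wave in the order of the first cannot be told apart from this either, since the steep genes peaked almost only at 10 h (110) and 11 h (116) and their Spearman rho of -0.659 restates the difference above. Among 1596 genes that rose then fell and reached at least 5 CPM between 5 and 13 h the rho was -0.182, and by first peak at 7, 8, 9, 10, 11 and 12 h 34.8, 70.3, 56.4, 62.0, 38.8 and 51.5% were higher at 16 h, in no steady order, which leaves it open, as these genes were picked for being low at 13 to 16 h.

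Ciliary, neuronal and neuropeptide genes were lower at 13 to 16 h than at 1 to 4 h. The share of the 50 most abundant genes in the raw counts of a library went from 18.2% to 17.2%. Before scaling this would raise other genes by 0.0176 (log2; a change of -0.0192 at most between single libraries of the 2 windows). The median log2 change over the 140 genes of the 3 lists was -0.650 by TMM and -0.651 by TMM without the 50 most abundant genes. Both argued against a few abundant genes as the cause. Growth of other tissues as the whole cause would lower the lists alike, which up to 13 to 16 h the ciliary median minus the neuronal one of -0.51 argued against (-0.85, quartiles -0.99 to -0.77, and -0.34, quartiles -0.53 to -0.01), with neuropeptide genes between them (-0.64, quartiles -0.89 to -0.32), and this gap came mainly from neuronal genes, whose median rose by 0.28 after 9 to 12 h (13 of 24 passed as higher and 1 as lower) while the ciliary one was at -0.05. Up to 9 to 12 h dilution cannot be told apart from other causes: the ciliary minus neuronal median was -0.00424 (-0.86 and -0.86, neuropeptides -0.79), but the steps to 5 to 8 h and then to 9 to 12 h were -0.44 and -0.47 for ciliary, -0.47 and -0.34 for neuronal and -0.61 and -0.18 for neuropeptide genes, where the ciliary and neuropeptide quartile ranges met only at their edges (-0.49 to -0.32 and -0.77 to -0.48, then -0.49 to -0.31 and -0.32 to -0.04) and neither median lay within the other. How much dilution contributes, and whether age after plating acts on these genes directly, stays open.

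Other splits of the same libraries were counted with the real one included. The real split gave the most genes for 13 to 16 h against 1 to 4 h (7566 genes, highest other split 376, 1 of 35 as large). The same held for 5 to 8 h against 1 to 4 h (3690, highest other 0) and for 9 to 12 h against 5 to 8 h (3339, highest other 98). It also held for 13 to 16 h against 9 to 12 h (4903, highest other 2316). The last of these others set 9 h with 14, 15 and 16 h, which points to a structure of the samples. The real hours also gave the most genes that rose then fell or fell then rose (3005, highest of the other draws 1010, 1 of 100) and the most with a time course (12344, highest other 597). Neighbouring hours resemble each other, so any smooth drift between libraries would give the real order the most genes. These counts argue against a random order of the libraries, but cannot tell time after plating from another drift.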
